A study of Caenorhabditis elegans with 2 samples.

How the data were processed

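The 2 libraries came from biological replicates of an anti-GFP immunoprecipitation in 1 group of young adult worms, sonicated to fragments of 200 to 800 bp per the labels. Replicates were taken as separate samples because the labels number them as biological replicates. The deposited text notes say that each replicate's regions, the pooled regions and the thresholded regions were made from aligned reads and a control alignment on assembly ce11, which is WBcel235. The peak caller, its settings, the IDR threshold and the aligner were not given in the sources used here. The control alignment was not analysed here.

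The deposited signal value of each region has no stated scale. In the pooled list it was within 10% of the sum of the replicates' values for 363 of the 392 thresholded regions found in both lists (ratio 0.607 to 1.2, median 0.994). The deposited −log10 q value rose with signal, with a Spearman's rho of 1.00 to 2 decimals across the pooled list and 0.866 across the thresholded set. It reached its maximum of 2.59 for 195 of the 393 thresholded regions, so signal was used to rank. Both are the authors' values and served only to describe and rank regions within a list. Each list except the thresholded one stops at 30000 regions, and nearly all regions of a list have 1 width (404 bp in replicate 1, 390 bp in the others). Exactly 10 thresholded regions are narrower, 7 of them among the 10 highest, and 0 lower-ranked regions are. All regions fall inside the reference chromosomes. Read depth is unknown, so no value here carries a counting error of reads.

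Lower-ranked regions are the 29491 of the pooled list that overlap no thresholded region. They served as background because they are where the caller could have placed a region. Regions and genes are not replicates, so p-values describe this set of calls. Genes came from the Ensembl annotation of WBcel235 and sequence from the RefSeq genome of that build. A promoter ran from 1000 bp upstream to 200 bp downstream of an annotated 5′ end of a protein-coding gene, and the other classes followed in the order 5′ untranslated, coding exon, 3′ untranslated, intron, noncoding gene and intergenic. Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family and exact binomial intervals at 95%. Odds ratio intervals are normal approximations on the log scale, with 0.5 added where a cell is 0.

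A total of 27 gene lists were tested on genes with any pooled region's summit in the window, 4 of them, the tRNA, microRNA, snoRNA and snRNA genes, among genes of every class. A gene is called bound when its window held a thresholded summit. The word is a label for that count only, since binding by the receptor was not tested against a control immunoprecipitation. Words were sought on either strand within 100 bp of a summit and in windows centred 400 bp to each side, with the larger p of both flanks kept. In the flank comparison of all 393 regions, of the 20 words CAAAGTCC, AGATAA, CACGTG, CAGCTG, GTAAACA, TGTTTGC, TAATTA, TGACTCA, TTGCGCAA, CCGGAAG, GGGCGGG and TATAAA did not pass. With replicate 2's list alone TGTTTGC (adjusted p = 0.0034), AGATAA (0.0223) and TAATTA (0.0328) passed that comparison by the exact McNemar test, as did TAATTA in the 196 regions of highest signal (0.0125), while TGATAA passed in neither setting (0.0837 and 0.295). GC content was compared by 100000 sign flips. Replicate sharing was set against 100 circular shifts, and loci against 10000 random genes.

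The named genes follow a rule fixed, like the lists, tests and most alternative settings, before the data were examined. It takes the 25 highest thresholded regions, up to 4 bound members of each list, nhr-27, nhr-270 and unc-119, and the 5 regions whose rank differs most between replicates. Where a list had few bound members all were named, and further ribosomal members were named after their values were seen. Distances of 200, 100 and 500 bp to small RNA genes, and settings that leave out regions near them, were chosen after seeing the data.

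Alternatives changed the set of regions (the 196 with the highest signal, or the 393 highest of a single replicate), the overlap rule, the promoter and summit windows, the background and the gene assignment. The steps were tested on simulated data. Random draws of regions gave any of the 23 protein-coding lists past the threshold in 1 of 100 draws (the 4 RNA gene lists were not simulated). The longest list, of 219 chemoreceptor genes with a listed region, passed in 95 of 100 draws when made 6 times likelier. Shorter lists were not favoured in any draw, so that rate does not hold for them. Random positions gave any word past the threshold in 0 of 20 draws, and AGGTCA written into 20% of windows passed in 20 of 20. Positions drawn at random do not carry the GC difference between summits and flanks, so that rate may not hold for summits. The 20% is far above the 2.54 points by which AGGTCA at summits exceeded its flanks, so detection of a small excess was not tested. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and, for the plots, matplotlib 3.10.9.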

Results

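The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) on whole worms of a Caenorhabditis elegans line that carries an integrated transgene for NHR-27, a nuclear hormone receptor, fused to green fluorescent protein. Antibody to the fluorescent protein pulled down the fusion protein with sonicated DNA from young adults at 78 h, of mixed sex. The 2 libraries are biological replicates of 1 group, so no comparison between conditions was possible. The labels disagree on the tagged protein: the description, the antibody label and the source name give nhr-27, while a free-text note on the strain gives NHR-270, and nhr-27 is used here. Each replicate had a list of 30000 regions, the pooled reads had another 30000, and an irreproducible discovery rate (IDR) threshold had left 393. The number of reads behind each region is unknown, since the lists hold signal values and not counts, and intervals below cover counting error over regions only.

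Of the 25 thresholded regions with the highest signal, 9 lay within 200 bp of a transfer RNA, small nucleolar RNA or small nuclear RNA gene (36%, exact 95% interval 18% to 57.5%), and those ranked 4, 17 and 19 were at promoters of ribosomal protein genes. All 393 were the 393 regions with the highest signal in the pooled list, in which signal ran from 28.5 to 430.2 with a median of 38.1, against a median of 109 in the thresholded set. Values with an SD are means of the replicates' own signals, which are on a lower scale than the pooled signal, and other signals are pooled. The 3 highest regions were in introns of protein-coding genes that host small nucleolar RNA (snoRNA) genes, RNAs that guide modification of other RNAs. The first, at V from 8500444 to 8500661 in pxn-1 over the snoRNA gene ZK994.7, had a signal of 207 ± 15.2 (SD, n = 2). The second, at V from 12303546 to 12303648 in frm-7 over C51F7.4, with its summit 69 bp from C51F7.3, had 167 ± 20.3 (SD, n = 2). The third, at V from 11314168 to 11314308 in cutl-18 over T03F7.8, had 150 ± 21.7 (SD, n = 2). The fourth lay 298 bp upstream of rpl-3, a large-subunit ribosomal protein gene, at III from 3867462 to 3867655, with 140 ± 6.86 (SD, n = 2). These first 4 regions, and the fifth, held the same ranks in each replicate's own list. The fifth was intergenic at the snoRNA gene W03C9.9, at II from 11960755 to 11960882, with 136 ± 8.42 (SD, n = 2). The sixth covered rpr-1, the RNA of ribonuclease P, in an intron of ints-8 at I from 13463768 to 13464157, with 124 ± 9.15 (SD, n = 2). The seventh lay between F44E5.4 and F44E5.5, at II from 11759378 to 11759584, with 124 ± 2.15 (SD, n = 2). The next 3 were not within 200 bp of a small RNA gene: an intronic region of mdt-26 at II from 5661815 to 5661952 (124 ± 20, SD, n = 2), the promoter of tasp-1 and K01G5.10 at III from 10759063 to 10759452 (114 ± 16.8, SD, n = 2), and a coding exon of dos-3 at III from 835832 to 836221 (113 ± 33.7, SD, n = 2). The eleventh was at sls-2.4, a spliced-leader RNA gene, at I from 4172328 to 4172451, with 115 ± 15.9 (SD, n = 2).

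Of the 393 highest regions of replicate 1, 172 overlapped one of the 393 highest of replicate 2 (43.8%, exact 95% interval 38.8% to 48.8%). Of the 393 thresholded regions, 170 were overlapped by a region among the 393 highest of both replicates (43.3%, exact 95% interval 38.3% to 48.3%), 260 by one of replicate 1 and 271 by one of replicate 2. Thresholded regions shifted at random along their chromosomes gave a mean of 0.44 and at most 2 shared with both in 100 shifts. The thresholded set was ranked on pooled signal, which was close to the sum of the replicates' values, so its overlap with each replicate is partly built in. Those shifts therefore do not measure agreement between replicates, and none were run for the 172. Almost all thresholded regions had some counterpart further down, 392 in the list of replicate 1 and 393 in that of replicate 2. Across the 392 regions found in both lists, which are not independent replicates, Spearman's rho of the replicates' signal was 0.13 (bootstrap 95% interval 0.0282 to 0.227) and Pearson's r of log10 signal was 0.24. In the 13824 lower-ranked regions found in both lists Spearman's rho was 0.202. The regions had been ranked on the pooled signal, which leaves out regions low in both replicates, and 73% of them were within 1.5-fold. The rank differed most for an exonic region of pgal-1 at I from 4911423 to 4911812, which ranked 51 in replicate 1 and 18224 in replicate 2. The next were an exonic region of glt-6 (ranks 10709 and 37), an intronic tRNA gene in pgp-1 (10510 and 93) and the pro-1 promoter (48 and 9470). A tRNA gene near F58D5.2, at rank 8965 in replicate 1, was the fifth, with ranks 8846 apart.

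**Figure D1:**
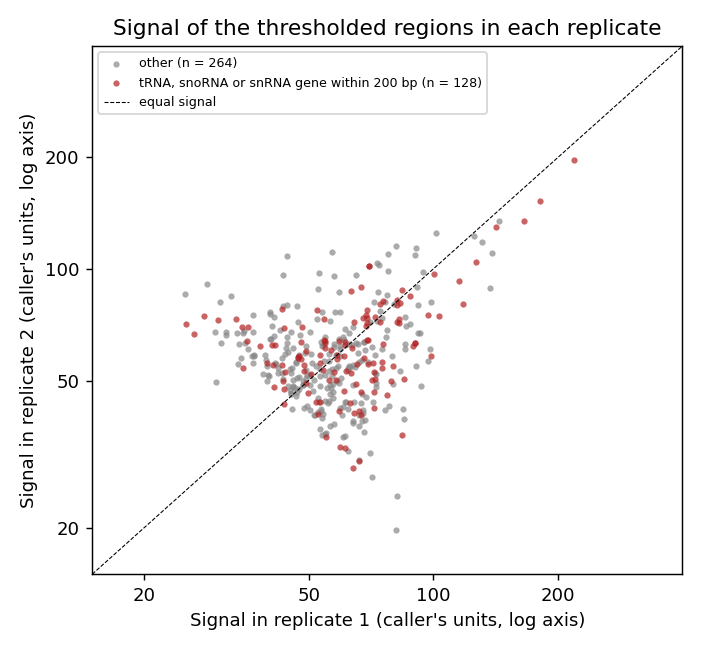
Signal of 392 thresholded regions in replicate 1 (x axis) and replicate 2 (y axis), in the caller's units on log axes, with the line of equal signal dashed. Red points lie within 200 bp of a tRNA, snoRNA or snRNA gene. Points spread to both sides of the line, with a Spearman's rho of 0.13 over all of them.

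Summits of thresholded regions lay near genes for transfer RNA (tRNA), snoRNA and small nuclear RNA (snRNA) far more often than summits of the 29491 lower-ranked regions. Within 200 bp of such a gene were 128 of 393 thresholded summits (32.6%, exact 95% interval 28% to 37.4%), against 1.7% of lower-ranked summits. The odds ratio was 27.9 (95% interval 22.2 to 35.1, Fisher's exact test, two-sided, adjusted p = 5.7e-116). For tRNA genes the counts were 74 thresholded regions and 1.14% of the lower-ranked, an odds ratio of 20.1. Near snoRNA genes lay 43 regions, against 0.404%, an odds ratio of 30.3. Near snRNA genes lay 11, against 0.156%, an odds ratio of 18.4. Regions at microRNA genes were few, 4 of 393 against 0.197% (odds ratio 5.22, Fisher's exact test, adjusted p = 0.0144). The distance of 200 bp was chosen after the lists had been seen. Counted by gene instead, with the window fixed beforehand, 92 of 479 tRNA genes with a listed region had a thresholded summit (odds ratio 7.25, adjusted p = 3.76e-39), as had 49 of 221 snoRNA genes (odds ratio 8.02, adjusted p = 1.68e-23) and 9 of 54 snRNA genes (odds ratio 5.23, adjusted p = 0.0014, all by Fisher's exact test). These odds ratios are lower than those by summit. Among snRNA genes, those with the highest signal after sls-2.4 were sls-2.1 (85.8 ± 22.7, SD, n = 2) and R07E5.16 (77.9 ± 6.79, SD, n = 2). The microRNA genes with the highest signal were mir-51 (72.8 ± 6.32, SD, n = 2) and the neighbours mir-54, mir-55 and mir-56, which share a region (65.1 ± 16, SD, n = 2).

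Promoters of protein-coding genes held 167 of the 393 summits (42.5%, exact 95% interval 37.6% to 47.5%), against 28.4% of lower-ranked summits. The odds ratio was 1.86 (95% interval 1.52 to 2.28, Fisher's exact test, two-sided, adjusted p = 1.32e-08). Coding exons held fewer, 39 summits or 9.92% against 28.6% (adjusted p = 3.57e-18, Fisher's exact test). Noncoding genes outside those classes held 28 summits or 7.12% against 3.15% (adjusted p = 0.000266, Fisher's exact test), and intergenic DNA 19.8% against 14.9% (adjusted p = 0.0144). Introns held 18.3% against 21.8%, which did not pass (adjusted p = 0.136, Fisher's exact test), nor did 5′ or 3′ untranslated regions. Of the 265 summits away from the small RNA genes, 128 were in promoters (48.3%).

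Ribosomal protein genes had the lowest p of the protein-coding gene lists, though heat shock protein genes had a higher share. Among the 52 with a listed region in the promoter window, 7 had a thresholded summit (13.5%), against 2.68% of the other 7232 genes (odds ratio 5.64, 95% interval 2.51 to 12.7, Fisher's exact test, adjusted p = 0.00346 over 27 lists). They were rpl-3, rpl-15 (99.9 ± 13.4, SD, n = 2), rpl-20 (93.6 ± 22.5, SD, n = 2), rps-1 (71.1 ± 1.28, SD, n = 2), rpl-35, rps-26 and rpl-12. Summits lay 5 to 940 bp upstream of the annotated 5′ ends. Those of rpl-15, rpl-20, rps-1 and rpl-12 also lay in the window of another protein-coding gene. Heat shock protein genes had 3 of 11 members bound (27.3%, odds ratio 13.4, adjusted p = 0.0157, Fisher's exact test): hsp-90 (75.1 ± 31.4, SD, n = 2), hsp-60 and hsp-1, all of them chaperones. The summits of hsp-90 and hsp-60 also lay in the window of another protein-coding gene. The heat shock call did not pass in 4 of 9 alternatives, among them the replicate 1 list alone (adjusted p = 0.0938) and the nearest 5′ end only (1 of 18 bound, adjusted p = 0.664, both by Fisher's exact test). Chemoreceptor genes, which encode sensory G protein-coupled receptors, had 0 of 219 bound, which allows a share of up to 1.37% (3 counts of the total) or 1.67% (upper limit of the exact 95% interval), against 2.85% of other genes (Fisher's exact test, adjusted p = 0.0218), and passed in 4 of 9 alternatives. The sre family was not in that list, and the region ranked 14 lay 618 bp upstream of sre-23. Its summit was also 59 bp from the snoRNA gene ZK265.10.

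The other lists did not pass with the main settings. Translation factor genes had 3 of 22 bound (eif-2Bgamma, iff-2 and eif-3.C, adjusted p = 0.0835, Fisher's exact test) and passed in 4 of 9 alternatives, with a lowest adjusted p of 0.00443, and proteasome and ubiquitin genes had 3 of 27 (ubq-1, pas-5 and ubc-6, adjusted p = 0.126). Among nuclear hormone receptor genes only nhr-47 was bound, 1 of 99, and microRNA genes had 9 of 117 bound (adjusted p = 0.127, Fisher's exact test), passing in 1 of 8 alternatives, with all annotated genes as background (odds ratio 3.26, adjusted p = 0.00979). Cytochrome P450, UGT and GST genes had 2 of 53 bound (gst-27 and cyp-43A1). Hypodermis markers had ajm-1, insulin and TGF-beta signalling had ins-39, ATPases and lysosome had cpr-9, and F-box and MATH proteins had fbxb-72. The regions of gst-27, cyp-43A1, ajm-1, cpr-9, eif-2Bgamma, pas-5 and rps-26 were also within 200 bp of a small RNA gene, and without such regions the cytochrome P450, UGT and GST list had 0 of 53 bound. No thresholded summit lay in the window of any gene among intestine markers (11 with a listed region), lipid metabolism (40), innate immunity (105), collagens and cuticle (62), muscle (21), neuron (34) and germline markers (21), homeobox factors (42), histones (22), GATA factors (6), major sperm proteins (6) or vitellogenins (2). Of these, innate immunity passed in 1 of 9 alternatives, with the nearest 5′ end only (0 of 198 against 2.85%, Fisher's exact test, adjusted p = 0.0362). The shorter lists cannot show a share near the 2.76% of all genes as different from 0.

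**Figure D2:**
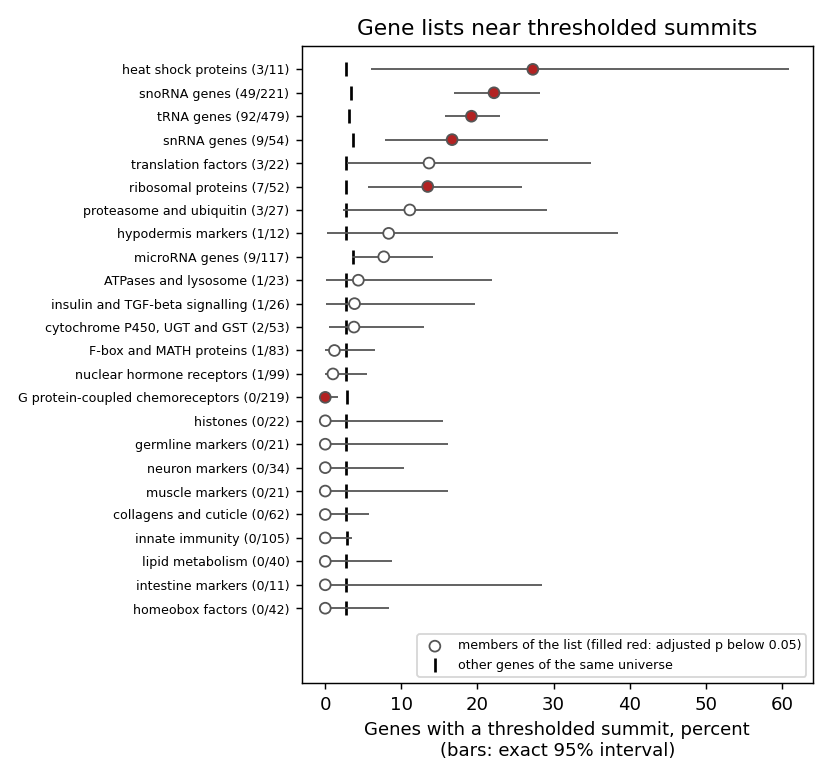
Percent of the genes in each list with a thresholded summit in the promoter window, among genes with any listed region there, for lists with at least 10 such genes, with exact 95% intervals. Vertical ticks give the other genes of the same universe. The tRNA, snoRNA, snRNA, ribosomal and heat shock lists lie above their ticks and chemoreceptors at 0 of 219.

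The word GAGAGA was more frequent at summits than in their flanks, and no nuclear receptor word passed that test. GAGAGA was in 27.5% of summit windows and 12.3% of flanking windows (exact McNemar test over 393 regions, adjusted p = 3.19e-06). AGGTCA, the core hexamer of many nuclear receptor sites, was in 6.87% against 4.33% (exact McNemar test, adjusted p = 0.769), and AGTTCA, AGTGCA and AAGGTCA did not pass either. TTTCAG, a splice acceptor word, was less frequent, 16.3% against 33.6% (exact McNemar test, adjusted p = 3.19e-06), as was the GATA word TGATAA, 9.67% against 20.4% (adjusted p = 0.00111), and AAAAAAAA, 9.67% against 22.5% (adjusted p = 1.97e-05). The TGATAA call was lost with replicate 2's list alone (-6.23 in place of -10.7 points, exact McNemar test, adjusted p = 0.0837) and in the 196 regions of highest signal (-10.5 points, adjusted p = 0.295). Mean GC content was 45% at summits and 36.1% in flanks, a difference of 8.87 percentage points (SE 0.447, n = 393, paired permutation test, two-sided, p = 1e-05, the smallest it can give). Lower-ranked summits were also richer in GC than their flanks, 41% against 36.1%, a difference of 4.89 points. Against lower-ranked summits of equal GC content and promoter class, TGATAA no longer passed (Fisher's exact test, adjusted p = 0.737), nor did AAAAAAAA, while GAGAGA (27.5% against 18.3%, 9.16 points) and TTTCAG (16.3% against 24.5%, -8.19 points) passed with smaller differences than the 15.1 and -17.3 points against flanks. In that comparison TGTTTGC (6.87% against 3.21%, odds ratio 2.23, adjusted p = 0.00647) and TATAAA (15.8% against 9.72%, odds ratio 1.74, adjusted p = 0.00443, both by Fisher's exact test) passed as well, neither of which had passed against flanks.

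Among all words of 6 bases, 143 were more frequent at summits and 77 less frequent at an adjusted p below 0.05. Of the 143, 122 had at least 4 G or C bases, and all 77 had at least 4 A or T bases. The lowest p belonged to CGAGAG, in 21.1% of summit windows and 5.22% of flanks, and CACGCG, in 12.7% and 1.53%. Both were also raised in the 265 regions without a small RNA gene. CGAACC, at 59.5% of the 74 regions near tRNA genes, was at 4.53% of those 265 regions against 2.83% of their flanks (exact McNemar p = 0.503).

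**Figure D3:**
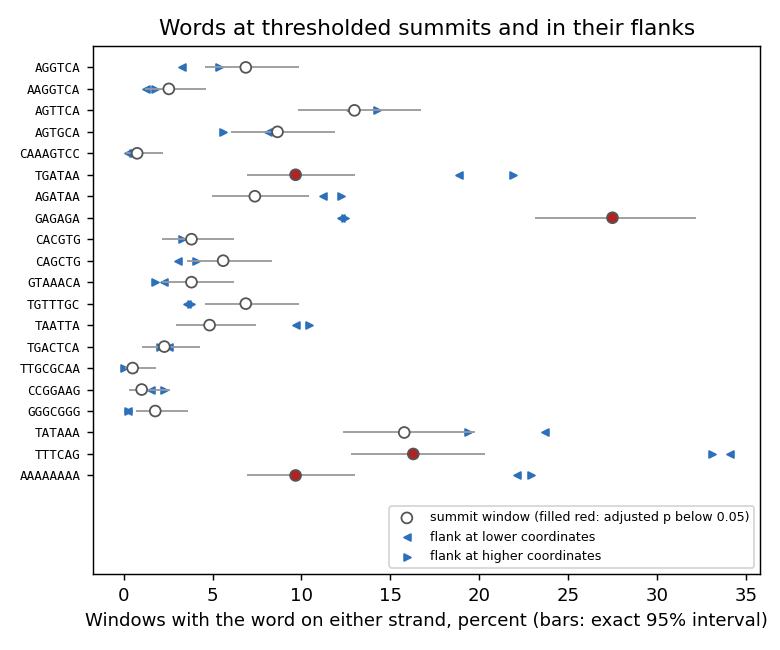
Percent of windows holding each of 20 words on either strand, at thresholded summits (circles, with exact 95% intervals) and in both flanking windows (triangles). GAGAGA lies to the right of its flanks, while TGATAA, TTTCAG and AAAAAAAA lie to the left.

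Chromosome V held fewer thresholded summits than its share of lower-ranked ones. It had 56 of 393 (14.2%) against 20% (odds ratio 0.666, 95% interval 0.502 to 0.886, Fisher's exact test, adjusted p = 0.0248 over 6 chromosomes). With replicate 1's list alone the adjusted p was 0.0585. Chromosome X had the most, 87 (22.1% against 18.2%), which did not pass (odds ratio 1.28, Fisher's exact test, adjusted p = 0.0968), nor did III, with 75 (adjusted p = 0.0968). With replicate 1's list alone X had 68 (17.3% against 18.4%, odds ratio 0.926), fewer than II with 70 and III with 73, so neither the order nor the direction for X held in both replicates. Central parts of the autosomes held 59.2% of autosomal summits against 54.5% (Fisher's exact test, p = 0.106).

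**Figure D4:**
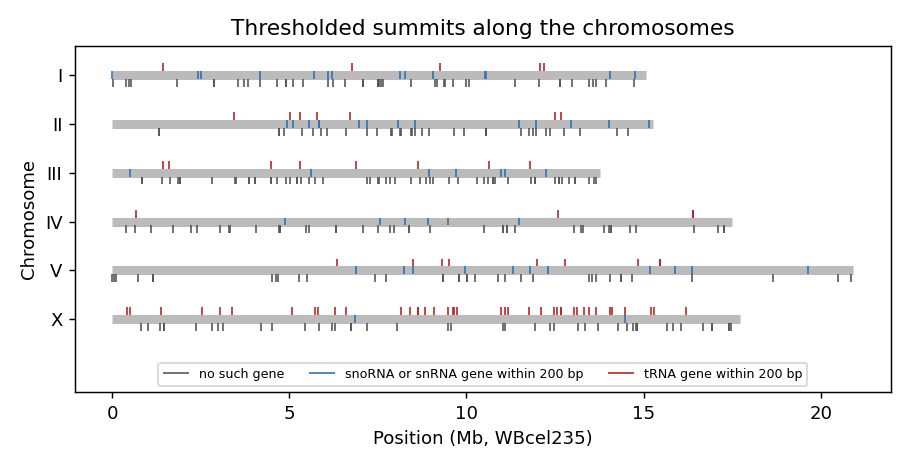
Positions of the 393 thresholded summits along the 6 nuclear chromosomes in megabases, with tRNA-gene regions in red and snoRNA or snRNA regions in blue. X carries 41 of the 74 regions near tRNA genes.

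The tagged gene's own locus held no thresholded region. Within 25 kb of nhr-27, at X from 12705563 to 12808318, the pooled list had 43 regions, of which the highest had a signal of 66.2 and rank 1661. That count was at percentile 99.97 of random protein-coding genes, but nhr-27 is long, and among windows of its length on X, a comparison chosen after the lists had been seen, it was at percentile 30.5. The same percentile was 79.7 in replicate 1's list (55 regions) and 29.1 in that of replicate 2 (42 regions), so the lists do not agree on its side of the median. By highest signal instead of count, nhr-27 was at percentile 11.3 of such windows in the pooled list. That percentile was 21.7 in replicate 1's list and 13.7 in replicate 2's. The neighbourhood of unc-119, whose rescue copy marks the transgene, at III from 10902641 to 10908935, had 14 regions, the highest at rank 6131. That of nhr-270, at V from 802546 to 804741, had 1, at rank 9960, a count at percentile 0.52 of random genes and 1.44 of windows of equal length. Replicate 1's list had 2 regions there (percentiles 0.62 and 1.58) and that of replicate 2 had 4 (1.51 and 2.785).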

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

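Settings that leave out regions near small RNA genes, or that compare loci with windows of equal length, were chosen after seeing the data. The promoter excess, the GC difference and the excess at small RNA genes kept their direction and passed in every alternative run, as did the ribosomal, tRNA, snoRNA and snRNA lists. No paired analysis was possible because there is 1 group. With the 196 regions of highest signal as the set, the number of regions was 196, 79.6% were shared with both replicates, 0 chromosomes passed, and autosome centres passed with an odds ratio of 1.44. Sharing was 64.1% with the 786 highest regions per replicate. Chromosomes past the threshold numbered 0 to 1 without each replicate, and the odds ratio of autosome centres was 1.26 to 1.41, past the threshold in both. With gene 5′ ends as background 3 chromosomes passed and X had an odds ratio of 1.795. X had 0.926 with replicate 1's list alone. Without regions near small RNA genes 2 lists passed of the protein-coding ones, the RNA lists being removed by construction. Against summits matched on GC and promoter class, TATAAA was 6.06 points higher at summits and AAAAAAAA 0.102 points higher, both opposite to the flank comparison; the cause was not tested. The percentile of the region count near nhr-27 was 30.5 among windows of equal length, which by construction takes its long gene body into account. It was 79.7 there in replicate 1's list and 29.1 in replicate 2's (81.1 and 12.9 at 10 kb). For unc-119 it was 39.4 at 25 kb, 21.9 at 10 kb, 24.1 to 26.4 without each replicate (52.2 in replicate 1's list and 31.8 in replicate 2's at 10 kb) and 25.1 among equal windows, and the cause was not tested. Read depth is unknown, so how far it limits these values cannot be stated.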

Other observations

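The patterns below were found in these data and tested on the same data. The test on single-copy snoRNA genes, the comparison of tRNA genes with and without a copy, and the count of X regions near nhr-27 were chosen after the result was seen. Thresholded regions near snoRNA genes had a median pooled signal of 122, those near tRNA genes 111 and regions away from small RNA genes 106. Among tRNA genes near a listed summit, 20.6% of those with an identical copy had a thresholded summit and 15.4% of those without, a difference that did not pass Fisher's exact test (odds ratio 1.43, p = 0.346).

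The excess of thresholded summits at tRNA, snoRNA and snRNA genes is the pattern that most needs an explanation. Reads shared between identical copies would leave no excess at genes whose exact sequence occurs once, if no gene with a copy lies beside them. Summits near the 140 of 612 tRNA genes that occur once had an odds ratio of 13.2 (95% interval 6.93 to 25.3), on 11 thresholded summits. Summits also near a tRNA gene with a copy were not left out, so shared reads there may add to this value. Of the snoRNA genes 343 of 346 occur once, and all 43 thresholded regions near a snoRNA gene stayed (odds ratio 30.6, 95% interval 21.2 to 44). Leaving out the others removed no thresholded region, so that value nearly repeats the one for all snoRNA genes. Near-identical copies were not counted, so part of the signal at tRNA and snoRNA genes may still be shared. GC content alone is argued against by an odds ratio of 23.9 over lower-ranked summits in the same GC bin (95% interval 16.3 to 34.9). Binding to receptor words at these genes stays open: AGGTCA was 5.86 points more frequent at the 128 summits than in their flanks, with a 95% interval of -0.628 to 12.3, and no control immunoprecipitation was analysed here.

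Chromosome X had 87 thresholded summits, an excess of 15.5 over the lower-ranked share that did not pass after adjustment and was absent from replicate 1's list (odds ratio 0.926). The transgene carrying nhr-27, an X-linked gene, is argued against as the source, since 0 of the 87 lay within 25 kb of nhr-27. Leaving out that neighbourhood removed no thresholded region, so the odds ratio of 1.29 it gave for X tests nothing. The number of tRNA genes on X is a candidate explanation that these values cannot test. X holds 276 of 612 tRNA genes, and 41 of its 87 regions lay within 200 bp of one. Replicate 1's list, with no excess on X, kept the tRNA excess by gene (71 of 448, odds ratio 6.75, Fisher's exact test, adjusted p = 3.72e-29). Without regions near tRNA genes the odds ratio of X was 0.773 (95% interval 0.565 to 1.06). Since 41 of those 74 regions are on X, leaving them out lowers it whatever the cause. With those regions left out III passed (odds ratio 1.48, Fisher's exact test, adjusted p = 0.0358) and V, with an odds ratio of 0.689 in place of 0.666, did not (adjusted p = 0.0501), as its p crossed the threshold with little change in size.

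GTTCGA, a word of the B box inside tRNA genes, was in 60.8% of summit windows within 200 bp of a tRNA gene and 7.43% of their flanks. In the 316 regions with no tRNA gene within 1000 bp it was 4.59 points more frequent at summits than in flanks, 11.4% against 6.8% (exact McNemar p = 0.0649), so whether tRNA genes alone carry the word cannot be told apart from a weaker excess elsewhere at this number of regions. Of the 36 such regions with the word, 13 were near a snoRNA or snRNA gene.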
